A study of Arabidopsis thaliana with 12 samples.

How the data were processed

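RNA from 12 Arabidopsis samples, 6 of wild type on glucose and 6 of the kn09 mutant on proline, was measured on a 1-channel array. The table used holds 1 value per feature and sample for 3439 features. The deposited values are intensities on a linear scale that the authors had scaled to a reference that the labels do not name. The scale ran from a floor at 0 to a ceiling just under 100, at which 1 to 6 features per sample stood. Scanner, background correction, normalization, spot averaging and filters are not given in the sources used here. Centring and the reference of the scale stay unknown; the intensities were taken as linear because none is negative and most lie near the floor. The medians of the wild type samples 1 to 6 were 0.208, 0.223, 0.224, 0.221, 0.137 and 0.141, and those of the kn09 samples 1 to 6 were 0.164, 0.165, 0.173, 0.174, 0.193 and 0.196.

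Sample groups and numbers came from the sample titles. Each feature was treated as 1 probe. Gene names came from GEO's annotation of the platform, updated through the Entrez identifier to the TAIR10.1 gene table; because the table names no genome build, no coordinates are printed. Of the 3439 features, 692 had 1 gene, 870 several and 1877 none in that annotation. The 692 stood for 691 distinct genes, and 690 of the 692 matched a current locus; features with several genes were not named.

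Values at 0 were set to the 1st percentile of the sample's positive values, and log2 was taken with no pseudocount. A positive value under that percentile therefore ranks below a zero. In kn09 sample 2, AT1G64510 at 0.00190 became -9.18 after normalization, while zeros became -7.32. Signs of dim probes can turn on this. AT5G52970 had mean intensities of 0.0205 in wild type and 0.00460 in kn09, but a log2 difference of 0.42. The medians of the log2 values ran from -2.66 to -2.04 and their interquartile ranges from 2.14 to 2.74, beyond the limit of 0.1 set before the data were examined, so the log2 values were quantile normalized between samples. Group differences were tested in limma 3.58.1 under R 4.3.3 with lmFit and eBayes, two-sided, with group as the only term and Benjamini-Hochberg adjustment over all 3439 probes at 0.05. Adjusted p-values and standard errors come from this fit, and fold changes are differences of the normalized log2 values; means and SDs are of the deposited intensities.

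Gene lists were tested with camera on 1 value per gene, with a preset correlation of 0.01, and adjusted over the lists with at least 4 measured members, the 17 fixed lists and the 8 added lists separately. With an estimated correlation the call of the photosynthesis list held and those of the 3 added lists ended. The named genes were fixed by rule: every measured proline metabolism gene, the 10 largest increases and 10 largest decreases past the threshold among single-gene probes, and up to 4 members of each tested list, those past the threshold with the largest difference or, if none passed, the 2 largest. The rule named 38 genes; 9 more, named after their values were seen, are PSBW, SBPASE, the 2 lone members of fixed lists, and 5 with a group mean intensity of at least 10.

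Alternatives fixed beforehand were no normalization, median centring, zeros as missing, a pseudocount, leaving out the dimmest 25% of probes, the replicate number as a block, eBayes with trend and robust settings, an exact permutation test over every split, fry and an estimated correlation for the lists, and leaving out each sample in turn. Pair means, a random block, leaving out wild type samples 1 and 2, the probes at the ceiling or those at 0 in more than 3 samples, and the 8 added lists were chosen after the data were seen.

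The fit was tested on 20 simulated sets of data in which 200 of the 3439 probes of this comparison were changed. The changed probes were drawn only from those above the dimmest 25%, so recovery among the dimmest probes was not tested. With independent samples the fit recovered on average 34.5% of changes of 1 and 70.7% of changes of 2 on the log2 scale. Of its calls, 5.58% were false. The share of variance common to a pair was set to 0.45, near the correlation of 0.447 estimated from the data, and to 0.7. At 0.45, 26.3% of the calls were false on average, against 7.20% with the random block and 6.73% with pair means, which recovered 31.4% of the changes of 2. At 0.7, 45.0% of the calls were false, against 6.85% with the random block. The recovered and false shares hold for 200 changed probes drawn in this way and do not carry over to the calls made in the data.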

Results

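RNA levels were measured on an array of 3439 features in Arabidopsis thaliana of the ecotype Wassilevskija. In 6 samples the plants were kn09, a mutant that the labels describe as hypersensitive to proline and unable to break proline down in the mitochondrion, with roots kept for 48 h on MS medium containing 100 mM proline. The other 6 samples were wild type, with roots kept for 48 h on the same medium containing 100 mM glucose. Genotype and the compound in the medium changed together, so every difference below belongs to mutant plus proline against wild type plus glucose, and none can be assigned to the mutation, to proline or to glucose alone. The labels do not name the mutated gene, do not say beyond the treated roots which tissue gave the RNA, and do not say whether the samples of a group came from separate plants. The p-values therefore measure only the spread between these samples, which may be technical. The median intensity per sample lay between 0.137 and 0.224 in the authors' units, and each sample held 175 to 475 features at 0. Of the features, 692 could be tied to a single gene; their number and that of the 12 samples limit the precision of what follows.

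The comparison of kn09 on proline with wild type on glucose asks which transcripts differ between these 2 combinations of genotype and medium. Several transcripts of the photosynthetic apparatus fell in kn09 on proline, LHB1B2, PSAN and PRK among them. LHB1B2 (AT2G34420), a chlorophyll a/b binding protein of the photosystem II antenna, had an intensity of 35.3 ± 5.65 (SD, n = 6) in wild type and 5.88 ± 1.06 (SD, n = 6) in kn09. This was a log2 difference of -2.63 ± 0.23 (SE), with an adjusted p of 8.80e-06 in limma. PSAN (AT5G64040), a subunit of photosystem I, fell from 7.65 ± 1.68 to 1.48 ± 0.381 (SD, n = 6 each), a log2 difference of -2.42 ± 0.23 (SE). PRK (AT1G32060), the phosphoribulokinase of the Calvin cycle, fell from 1.34 ± 0.347 to 0.334 ± 0.110, a log2 difference of -2.06 ± 0.27. Transcripts that rose included CML41 (AT3G50770), a calmodulin-like protein, from 0.199 ± 0.111 to 1.46 ± 0.367 (SD, n = 6 each), and XERICO (AT2G04240), a RING-H2 protein connected with abscisic acid, from 4.22 ± 0.934 to 11.0 ± 2.63.

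**Figure D1:**
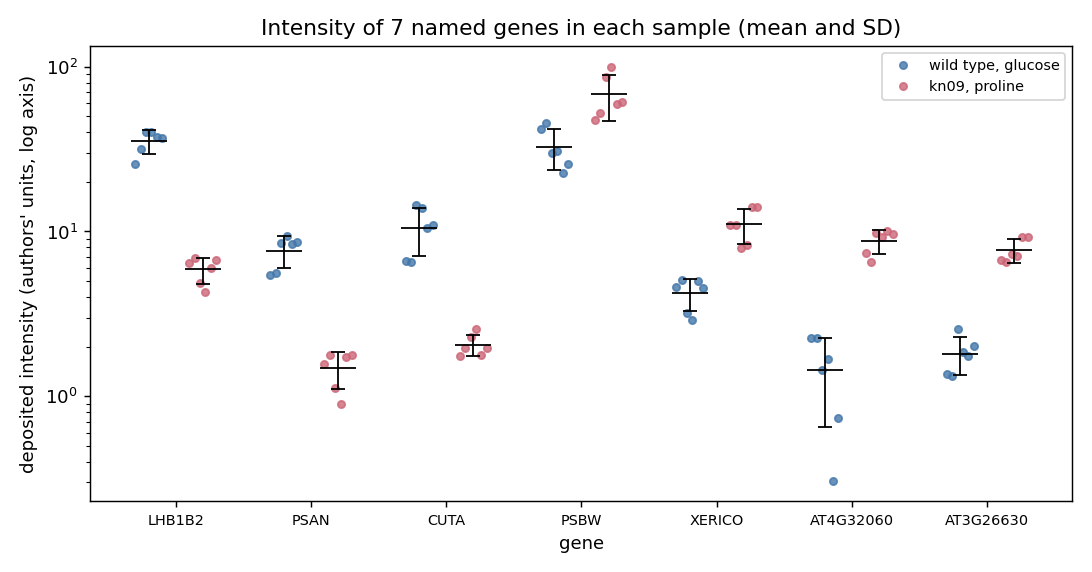
Deposited intensity of 7 genes (log axis, authors' units) in each of the 6 wild type samples on glucose and the 6 kn09 samples on proline, with the mean and SD of each group. LHB1B2 lay between 25.8 and 40.3 in wild type and between 4.28 and 6.91 in kn09, while XERICO lay between 2.90 and 5.10 in wild type and between 7.94 and 14.0 in kn09.

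Over the whole array, 951 of 3439 probes passed an adjusted p of 0.05 in limma, 484 higher and 467 lower in kn09 on proline. The balance of directions depended on the processing. Without normalization 442 were higher and 526 lower, and with zeros as missing 426 were higher and 574 lower. Within each group, samples 1 and 2, 3 and 4, and 5 and 6 resembled each other more than most other samples of the group did. With the members of these pairs averaged, leaving 3 values against 3, 202 probes passed, 80 higher and 122 lower. With the pairs as a random block, 620 passed, 343 higher and 277 lower; both fits were chosen after the data were seen. Among the 692 single-gene probes, 179 passed, 90 higher and 89 lower, and 38 of the 692 passed on the pair means. Of the 42 genes named here that passed, 23 did not pass on the pair means, among them XERICO with an adjusted p of 0.108, AT4G32060 with 0.0509 and LPA19 with 0.0879. With the pairs as a random block 10 did not pass: PSBW, AT4G01310, AT5G41960, AT3G54210, AT4G17070, AT1G67930, AT4G03150, AT5G11550, AT4G29750 and AT1G76450, with adjusted p from 0.0511 to 0.203.

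The photosynthesis list was the only one of the 17 lists fixed before the data were examined that had 4 or more measured members. All 4 members had lower values in kn09 on proline; LHB1B2, PSAN and PRK fell, and both the count over all probes and the count adjusted over the list alone came to 3. SBPASE (AT3G55800), the sedoheptulose-bisphosphatase of the Calvin cycle, did not pass, with a log2 difference of -2.08 ± 0.96 (SE), an adjusted p of 0.129 and a value of 0 in 2 of the 6 kn09 samples; with zeros as missing the difference was -0.64, without kn09 sample 6 it was -1.39 and without kn09 sample 2 it was -1.46. The list shift had an adjusted p of 8.30e-05 in camera with its preset correlation, and an adjusted p = 0.00289 with an estimated correlation. LHB1B2, PSAN and PRK also passed on the pair means.

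Of 11 proline metabolism genes on the fixed lists, 0 had a single-gene probe. Of the starvation list, the single measured gene was ETFQO (AT2G43400), an electron-transfer flavoprotein oxidoreductase of the mitochondrion, with 0.0913 ± 0.0508 in wild type and 0.104 ± 0.0622 in kn09 (SD, n = 6 each) and an adjusted p of 0.821 in limma. Its sign turned when the samples were centred on their medians or left without normalization. Of the glycolysis and fermentation list, the single measured gene was the lactate dehydrogenase AT4G17260, with a log2 difference of 0.38 ± 0.46 (SE) and an adjusted p of 0.575. The other 14 lists had 0 measured members.

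A further 8 lists were written from the gene names on the array before any difference was computed, but after the annotation and the brightest features had been seen. Of the 13 genes of the thylakoid light reactions, 6 fell, 1 rose and 6 did not pass. Besides LHB1B2 and PSAN, LPA19 (AT1G05385), a photosystem II assembly factor, fell, with a log2 difference of -1.49 ± 0.29 (SE). AT1G76450, a protein of the PsbP family, fell by 2.30 ± 0.80 (SE) with an adjusted p of 0.0497 and 2 of its 6 kn09 values at 0; its log2 difference was -1.54 with a pseudocount and -1.33 with zeros as missing. It lost its call with the replicate block, at 0.0964, and without any 1 of 9 of the 12 samples, with adjusted p up to 0.0953. The gene that rose was PSBW (AT2G30570), the W subunit of photosystem II, named here after its value was seen. It went from 32.7 ± 8.99 to 67.8 ± 20.8 (SD, n = 6 each), a log2 difference of 0.92 ± 0.28 (SE) with an adjusted p of 0.0267 in limma; 1 of the 6 kn09 values stood at the ceiling, so its level there is a lower limit. PSBW lost its call with the pairs as a random block, with an adjusted p of 0.0511, with the replicate block, at 0.0885, and without any 1 of 6 of the 12 samples, with adjusted p up to 0.0609. The shift of this list had an adjusted p of 0.0167 in camera, and adjusted p = 0.0680 with an estimated correlation. Of its members 2 fell on the pair means and 5 with the random block, and 0 rose in either.

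Of 6 plastid ribosomal protein genes, 4 fell and 0 rose. AT1G64510, the plastid protein S6, had an intensity of 0.216 ± 0.0828 (SD, n = 6) in wild type and was listed at 0 in 4 of the 6 kn09 samples. AT1G29070, the plastid protein L34, had 0.103 ± 0.0361 in wild type and stood at 0 in 5 of the 6 kn09 samples. The log2 differences of AT1G64510 and AT1G29070, -4.88 ± 0.64 (SE) and -3.21 ± 0.65 (SE), rest on the value given to those zeros. AT4G01310 fell by 1.01 ± 0.26 (SE) and AT3G54210 fell by 1.52 ± 0.50 (SE). AT3G54210 lost its call without any 1 of 7 of the 12 samples, with adjusted p up to 0.0762, and with no normalization, at 0.0629, or median centring, at 0.0693. The list had an adjusted p of 0.0261 in camera, and adjusted p = 0.0966 with an estimated correlation; 2 members fell on the pair means and 2 with the random block. Without the dimmest 25% of probes 3 members were left, too few to test. The kn09 samples held 317 to 475 features at 0 and the wild type samples 175 to 265.

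Of 20 genes for pentatricopeptide repeat and mTERF proteins, families that act on organelle RNA and transcription, 3 rose, 1 fell and 16 did not pass. AT3G26630 rose from 1.82 ± 0.462 to 7.71 ± 1.23 (SD, n = 6 each), a log2 difference of 2.03 ± 0.20 (SE). The mTERF gene AT5G55580 rose by 1.83 ± 0.25 (SE) on the log2 scale and OTP85 (AT2G02980), an RNA editing factor, by 1.68 ± 0.38 (SE). AT4G14050 fell by 1.33 ± 0.34 (SE). The list had an adjusted p of 0.0261 upward in camera, and adjusted p = 0.133 with an estimated correlation; without the dimmest 25% of probes it was 0.0751. On the pair means 2 rose and 0 fell, with OTP85 at an adjusted p of 0.0923 and AT4G14050 at 0.156.

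The remaining 5 added lists did not pass in camera. Among their members that passed in limma, AT1G05340, AT5G52810, GLDH and AT5G63290 did not pass on the pair means, with adjusted p of 0.0685, 0.145, 0.141 and 0.108. Of 10 stress and hormone response genes, 3 rose, CML41, XERICO and AT1G05340, the last from 0.112 ± 0.0513 to 0.262 ± 0.0523, and the list had an adjusted p of 0.0913. Of 9 genes of amino acid, purine and thiamine synthesis, 2 rose, with the list at an adjusted p of 0.0913. These were AT2G35390, a phosphoribosyl pyrophosphate synthetase, by 2.81 ± 0.23 (SE), and AT5G52810, also known as SARD4, by 1.12 ± 0.29 (SE). Of 10 genes of carbon fixation and plastid redox, 2 fell, PRK and GLDH (AT3G47930), the mitochondrial enzyme of the last step of ascorbate synthesis, which fell by 1.58 ± 0.41 (SE). That list had an adjusted p of 0.267. Of 6 genes of tetrapyrrole and carotenoid synthesis, 1 rose, AT5G63290, with a log2 difference of 1.34 ± 0.27 (SE). The adjusted p of its list was 0.920; the median of its members was -0.04 and the mean -0.28, while the camera test ran upward. Of 4 genes of glycosyl hydrolase family 9, 0 passed; GH9B11 (AT2G44560) had a log2 difference of -1.87 ± 1.25 (SE), which was -0.55 without kn09 sample 4 and -0.77 with a pseudocount, and GH9B16 (AT4G38990) of -1.04 ± 0.84 (SE), which was -0.33 with zeros as missing, and the list had an adjusted p of 0.587.

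**Figure D2:**
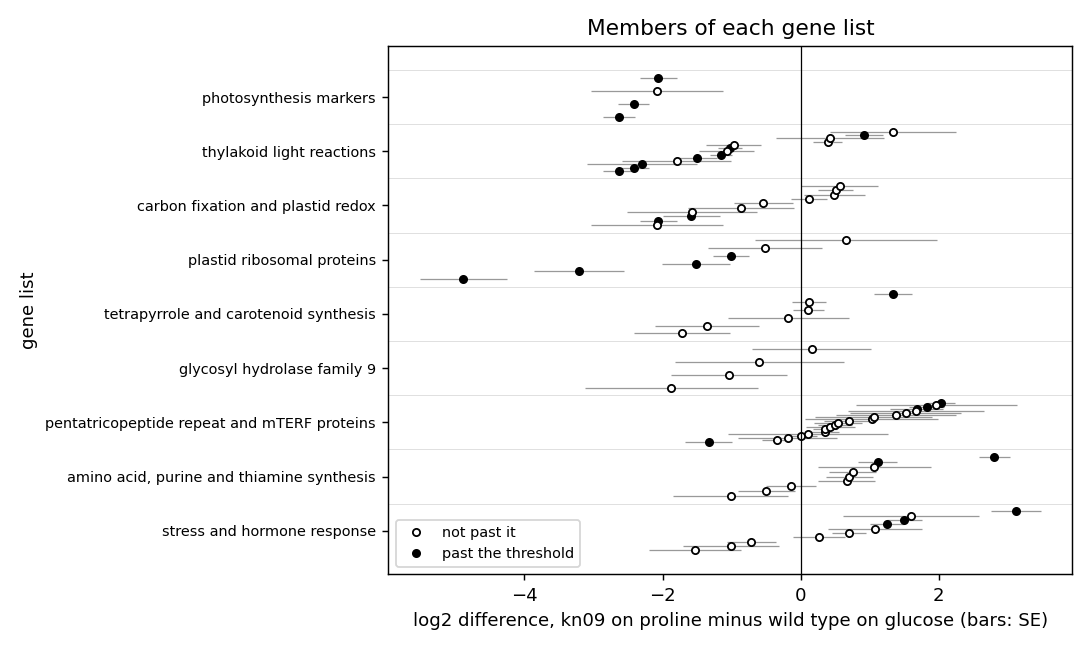
Log2 difference of kn09 on proline minus wild type on glucose for each measured member of the photosynthesis list and the 8 added lists, with the SE from limma; filled points passed an adjusted p of 0.05. All 4 photosynthesis markers lie below 0, and 17 of the 20 pentatricopeptide repeat and mTERF genes lie above 0 (16 of 20 when the samples were centred on their medians or not normalized). Among these 17, AT2G46050, AT1G62010, AT3G22690 and AT5G39980 had lower mean deposited intensities in kn09 than in wild type. Wild type values at 0 numbered 1, 1, 3 and 2 for these genes, so their signs can depend on the value given to a zero.

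Among single-gene probes, the largest increases past the threshold were AT4G13550, a lipase gene, with a log2 difference of 3.32 ± 0.62 (SE), FBL17 (AT3G54650), an F-box gene of the cell cycle, with 3.30 ± 0.69, AT5G17280 with 3.15 ± 0.20, CML41 with 3.12 ± 0.37, and AT2G35390. FBL17 stood at 0 in 4 of the 6 wild type samples, so its size and rank depend on the value given to a zero: with a pseudocount the log2 difference of FBL17 was 1.88, and without wild type sample 2 it was 4.03. These were followed by AT2G30100 with a log2 difference of 2.79 ± 0.58 (SE), AT1G72890 with 2.73 ± 0.47, AT4G32060 with 2.73 ± 0.43, AT5G41960 with 2.72 ± 0.76 and AT2G23160 with 2.70 ± 0.64. In limma on the pair means AT2G30100, AT4G32060, AT5G41960 and AT2G23160 did not pass, with adjusted p of 0.0923, 0.0509, 0.125 and 0.108. The difference of AT4G13550 was 2.67 without wild type sample 6, that of AT5G41960 was 2.05 without wild type sample 3, and that of AT2G23160 was 3.29 without wild type sample 2 and 1.89 with a pseudocount. AT4G32060, a calcium-binding regulator of mitochondrial calcium uptake, went from 1.45 ± 0.796 to 8.80 ± 1.47 (SD, n = 6 each).

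The largest decreases began with AT1G64510, followed by the aldo-keto reductase gene AT1G04420 with a log2 difference of -3.44 ± 0.80 (SE), AT3G54930 with -3.32 ± 0.17, AT5G02710 with -3.28 ± 0.59, AT1G29070 and AT5G11550 with -3.20 ± 0.92. Then came CHL (AT3G47860), the chloroplast lipocalin, with a log2 difference of -2.89 ± 0.76 (SE), AT4G29750 with -2.81 ± 0.86, AT4G03150 with -2.68 ± 0.80 and AT1G67930 with -2.68 ± 0.73. AT3G54930, a regulatory subunit of protein phosphatase 2A, had a mean intensity of 7.07 in wild type and 0.759 in kn09, with the 6 kn09 samples between 0.570 and 0.892 and the 6 wild type samples between 6.18 and 8.13, and was the only one of these 10 with 0 zeros in kn09. In kn09, AT1G04420 was listed at 0 in 5 of 6 samples, AT5G02710 and AT1G67930 in 4, CHL in 3, AT4G29750 and AT4G03150 in 2 and AT5G11550 in 1, so these sizes, and with them the order and the choice of the 10, depend on the value given to a zero. AT1G04420 had a log2 difference of -4.19 without kn09 sample 2, and AT5G11550 of -2.56 without kn09 sample 4. In limma on the pair means AT1G04420, CHL, AT4G03150 and AT1G67930 did not pass, with adjusted p of 0.0710, 0.126, 0.0699 and 0.0586. With a pseudocount the difference of AT1G64510 was -2.78, that of AT1G04420 -2.03, and those of the other 7 with zeros lay between -2.26 and -1.51. On that scale AT3G54930 fell the most of the genes named here, with a log2 difference of -3.28, ahead of AT1G64510, LHB1B2 at -2.62, PSAN at -2.40 and CUTA (AT2G33740) at -2.36. AT4G29750 lost its call without any 1 of 6 of the 12 samples, with adjusted p up to 0.0618, and AT4G03150 without kn09 sample 2, at 0.0517, or wild type sample 5, at 0.0546.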

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

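The tests of mixed RNA, of a lower signal floor and of an even loss of green tissue were chosen after the values they concern had been seen. The first 2 of these replaced earlier forms: with deposited in place of normalized intensities the shifts of the mixing test were 16.4% and 39.3%. The floor test gave 81.2% with probes chosen as dim in wild type, which by itself favours increases, and 47.7% on normalized values, which removes a floor shared by all dim probes; both forms were void. The test of green tissue was first run on all 13 genes with the limma errors, and also required a gene that rose. The value of that first form is not given here. In 102 sets of 6 values, 7 held a sample far from the others, about as many as the 1 in 20 that chance gives. AT4G13550 stood at 0.00760 in wild type sample 6, below 0.0598 to 0.196 in the others. FBL17 stood at 0.130 in wild type sample 2, above 0 to 0.0389 in the others. In kn09 sample 2, AT1G04420 stood at 0.101 while the others were at 0. AT1G29070 stood at 0.0515 in wild type sample 3, below 0.0903 to 0.163, and at 0.0425 in kn09 sample 5 while the others were at 0. GH9B11 stood at 0.000202 in kn09 sample 4, below 0.0556 to 0.131, and ETFQO at 0 in that sample, below 0.0595 to 0.163.

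Of 100 splits drawn from the 462 possible, 1 gave as many as the 951 probes, the real one, and the highest of the others gave 3. That would exclude chance only if the 12 samples were independent. The correlation of 0.447 within the sample pairs goes against this, so chance is not excluded for the count. With the sample pairs kept whole and averaged there are 10 splits, too few for a share under 0.05; of these, 1 gave as many as the 202 probes of the real one, and the highest other gave 0.

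The lower values of thylakoid genes were weighed first. Of the 13 genes 9 were lower and 4 higher, and past the threshold 6 fell and 1 rose. The camera call of this list ended with an estimated correlation, at an adjusted p of 0.0680. A different scaling of the samples is argued against, since the median log2 difference of the 13 genes was at most -1.02 under quantile, median or no scaling. The 9 genes with no value at 0 differed more than their errors allow, from -2.63 for LHB1B2 to 0.92 for PSBW. The heterogeneity chi-square p was 4.79e-12, and 8.68e-08 without PSBW, which reached the ceiling in 1 sample. This argues against 1 equal fall of all 9 genes. It cannot decide on a loss of green tissue, since genes with signal from other tissue as well would fall by different amounts. A smaller share of green tissue, even or uneven, stays open, and so do the mutation, proline and glucose, which the design does not separate.

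Wild type samples 1 and 2 lay nearer the kn09 samples, with a mean rank correlation of 0.795, than wild type samples 3 to 6 did, with 0.736. The mean rank correlation of samples 1 and 2 with wild type samples 3 to 6 was 0.798, about the same as with the kn09 samples. Dim probes do not account for the gap to wild type samples 3 to 6, since in the brightest 25% of probes it was 0.192. Mixed-in kn09 RNA alone would move higher and lower probes by the same share. The median shift was 14.1% (95% interval 8.89 to 18.5) over the probes called higher and 42.4% (36.6 to 47.6) over those called lower. These probes were called in a fit that included samples 1 and 2, which can bias both shares. Mixing, alone or with another difference, is therefore not excluded. No biological explanation was tested, since the labels give none for these samples, and a difference between the sample pairs stays open.

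The kn09 samples held 317 to 475 values at 0 and the wild type samples 175 to 265. Zeros do not make most of the decreases: 14.3% of the probes called lower held any value at 0. A lower floor of signal in kn09 would lower every dim probe, and of the 98 calls made on the deposited values in the dimmest 25% of probes, 7.14% were higher (95% exact interval 2.92 to 14.2). This goes with a lower floor without settling it, so a lower floor and a real loss of weak transcripts in kn09 on proline cannot be told apart for these probes.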

How the results depend on the processing

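The pair fits and the settings without wild type samples 1 and 2, without probes at the ceiling or often at 0 were chosen after the data were seen. Pair means gave 202 probes, 80 higher and 122 lower, with fewer samples; the pair random block gave 620, of which 277 were lower. In all other settings the count lay between 789 and 1152 and 0 of the calls that each setting tested, 886 to 951 of the 951, changed sign. In 4 of these settings the differences are those of the main fit, so no sign could change. They are the replicate block, the trend and robust settings, the exact permutation test and the set without the dimmest 25% of probes. Leaving out 1 sample gave 789 to 1010 probes, 422 to 498 higher and 364 to 514 lower. Replicate numbers were shared by the groups. Same-numbered samples deviated together with weak but positive correlations of 0.0226 to 0.0937 and were not taken as pairs in the main fit. With the replicate block 815 probes passed. Of the samples, 5 of 6 wild type and 6 of 6 kn09 correlated best with their own number. This is a hint, from the data alone, that same-numbered samples share something that the main fit leaves out. The photosynthesis list passed in every setting run for lists. Of the added lists 3 passed, and 0 did with an estimated correlation. The estimate was -0.046 for thylakoid light reactions and -0.086 for plastid ribosomal proteins, both under the preset 0.01. For pentatricopeptide repeat and mTERF proteins it was 0.034. A higher correlation therefore did not end the calls of the thylakoid and ribosomal lists. Without the dimmest 25% of probes 1 list passed, thylakoid light reactions, while plastid ribosomal proteins had 3 members left, too few to test. In fry, which does not compare a list with other genes, 6 passed. The cause of these changes was not otherwise tested. ETFQO reversed to -0.096 with no normalization, -0.0089 with median centring and -0.67 without wild type samples 1 and 2, and ran from -0.36, without wild type sample 2, to 1.08 when 1 sample was left out. The median difference of all probes was -0.03 after quantile normalization, -0.27 after median centring and -0.36 without normalization. Of 42 named genes past the threshold, 36 kept it whichever 1 sample was left out, but 23 lost it on pair means, 10 with the pair random block, 5 without wild type samples 1 and 2, 4 with the replicate block, 2 with median centring, 2 of the 36 that could be tested with zeros as missing, 1 with no normalization and 1 in the exact permutation test. No value was missing, so a filter on missing values was not run. Signal near 0 limits the folds of dim genes.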

Other observations

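Several of the brightest single-gene probes also differed; they were named after their values were seen, as those past the threshold with a group mean of at least 10. CUTA (AT2G33740), named for a copper tolerance protein of bacteria, fell from 10.5 ± 3.44 to 2.05 ± 0.305 (SD, n = 6 each), a log2 difference of -2.38 ± 0.24 (SE) with an adjusted p of 2.64e-05 in limma. AT1G62250 fell from 10.2 ± 3.26 to 2.33 ± 0.242, a log2 difference of -2.13 ± 0.23. CUTA and AT1G62250 were lower in 6 of 6 kn09 samples than in any wild type sample and passed on the pair means as well. AT4G17070 rose from 12.7 ± 5.74 to 30.4 ± 8.05 with an adjusted p of 0.0159, and AT4G19900 from 4.31 ± 3.01 to 10.4 ± 0.551 with 0.0211. Wild type samples 1 and 2 had 8.03 and 8.34 for AT4G19900, and wild type samples 3 to 6 had at most 2.64. AT3G09850 rose from 39.5 ± 16.1 to 75.3 ± 19.9 with 0.0251; 2 of its 6 kn09 values stood at the ceiling, so its level there is a lower limit. With pair means these 3 increases had adjusted p of 0.0770, 0.184 and 0.221, and AT3G09850 lost its call without kn09 sample 1, kn09 sample 2 or wild type sample 4, with adjusted p up to 0.0530, and with median centring, at 0.0733.

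The largest changes among features with a group mean of at least 50 were on probes that the annotation ties to several genes or to none, so they carry no gene name here. Probe 4399 went from 7.01 ± 1.76 to 93.2 ± 6.59 (SD, n = 6 each), with 2 of the 6 kn09 samples at the ceiling, so its level there is a lower limit. Its log2 difference of 3.51 is of the normalized values with the ceiling taken as the level. Probe 812 went from 80.3 ± 12.7 to 14.7 ± 1.33 and probe 621 from 66.2 ± 8.64 to 11.1 ± 1.23. Probe 910 stood at the ceiling in all 6 kn09 samples, so its level there is a lower limit and the size of its change cannot be ranked. It was 1.77-fold higher in kn09 than in wild type by the means of the normalized log2 values, with the ceiling taken as its level. Its adjusted p of 0.0220 in limma became 0.0513 with a pair random block.

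After quantile normalization, calls lay mostly among bright probes, with increases and decreases in similar numbers. That step gives every sample the same distribution of values, which by itself favours similar numbers in both directions. In the dimmest 25% of probes 31 were higher and 34 lower, whereas on the deposited values 7 of 98 calls there were higher, and in the brightest 25% 251 of the normalized calls were higher and 240 lower. The groups did not overlap in 624 of the 3439 probes. Chance gives 0.216% for 6 independent samples against 6, and at most 10% if the sample pairs are kept whole. The 10% is reached if both members of each pair have the same value.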
